A study of Homo sapiens with 203 samples.

How the data were processed

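The data were expression arrays of human tissue RNA. The 203 arrays held 21 liver biopsies of a development set, 10 liver biopsies of a later validation set, 39 arrays of RNA mixed from the first pair of a liver and a breast cancer (pair 0), 110 arrays of RNA mixed from 11 further pairs (pairs 1 to 11), and 23 metastatic breast cancer biopsies. Pair 0 was mixed at 13 levels of liver RNA and measured in 3 technical replicates per level. Pairs 1 to 11 were mixed at 10 levels with 1 array per level and pair. Their groups were taken from the sample cohort, tissue and liver percentage in the labels. The primary breast cancer biopsies named in the series design were not analysed here, and the undiluted tumour RNA of pairs 1 to 11 stood in as tumour without added liver.

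Per the labels' protocols, total RNA was purified on Qiagen RNeasy columns and made into biotin-labelled cRNA by 1 round of T7 amplification. Per the submitters' processing notes, the signals came from MAS5, the Affymetrix summary of a probe set; its version, its scaling target and any further scaling are not given in the sources used here. The authors deposited the signals as log2 values, 1 column per sample and 1 line per probe set, for 22215 probe sets. The values ran from -4.53 to 19.92, and array medians lay between 8.03 and 8.62, so each array carried a scaling of its own and the arrays had not been forced to 1 distribution. The scale of the levels was therefore relative, and a change in a few abundant transcripts could move the others. A second deposited table of log2 values held 203 entries, of which 188 were matched to a sample by name. The other 15 were not used. Over 46 probe sets that were compared, the largest difference between both tables was 4.998e-09, so the second table was used only for its control probe sets at the 3-prime and 5-prime parts of ACTB and GAPDH.

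A probe set was named through the platform annotation. It gave 1 gene symbol for 19065 probe sets, several for 1043 and none for 2107, and no gene was named from a probe set with several. Each of 11963 genes was represented by the single-symbol probe set with the highest mean log2 value over the 110 arrays of pairs 1 to 11; 4310 genes had more than 1 probe set. No filter was set on low values. Levels of XIST and Y-linked genes were left out of every named result.

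Differences between groups were fitted on the log2 values with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probe sets, and a probe set was called at an adjusted p under 0.05. Each fit held only the groups compared. The exception was pair 0, in which all 39 arrays shared 1 estimate of the technical spread. Undiluted livers were compared with undiluted tumours over pairs 1 to 11, and again in 2 splits that shared no array: the development livers against the tumours of odd-numbered pairs, and the validation livers against those of even-numbered pairs. The liver sets were compared with each other, the mixtures of each level with the undiluted tumours, and the metastatic biopsies with the undiluted tumours. Within the metastatic biopsies, each probe set was fitted on the liver index as a continuous covariate. The single probe set that represented each index gene was left out, which left 22197. Other probe sets of the index genes stayed in. The mixture fits had the pair as a block, because the titles state that mixtures of a pair hold RNA of the same samples. Same-pair correlations of the deviations from the group means were 0.398 to 0.600 at 5% and 0.272 to 0.476 at 50%, and in 11 of 11 pairs the best partner was the own pair. For undiluted livers and tumours they were -0.0240 to 0.0662, so the main test there had no block; for the technical replicate numbers of pair 0 they were -0.0314 to 0.00181.

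There were 25 gene lists, all written before the data were examined and none chosen on these samples: a liver index of 20 hepatocyte genes, a second index of 30 others, plasma proteins, cytochrome P450 and xenobiotic enzymes, urea cycle and amino acid enzymes, bile acid genes, the acute phase, Kupffer cells and macrophages, sinusoidal endothelium, cholangiocytes, luminal and oestrogen receptor genes, the HER2 amplicon, basal markers, proliferation, stroma and extracellular matrix, lymphocytes, adipocytes, lung, skin, brain, muscle, blood (erythroid and granulocyte), early response (immediate early and heat shock), ribosomal proteins, and 4 genes assayed in breast cancer (ESR1, PGR, ERBB2 and MKI67). The genes of the study's own index were not used here. The lists share members, for example KRT19 in the luminal and cholangiocyte lists. Most measured plasma protein genes are also genes of the liver index, as are some acute phase and urea cycle genes. Counts for the index and the plasma proteins are therefore not separate evidence. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation.

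The liver index of an array was the mean log2 value of the 18 measured genes of its list. A calibration curve, index = log2(a + b p / (p + K)) with p the nominal percentage of liver RNA, was fitted by least squares to the 39 arrays of pair 0 and inverted to give an estimated percentage, held between 0 and 100. Its error was measured on the 110 arrays of pairs 1 to 11, with exact two-sided sign-flip tests over the 11 pairs (2048 flips, smallest p 0.000977) adjusted over the 10 levels. An effective liver fraction, which uses no index, was the median over probe sets at least 8-fold apart between the undiluted liver and tumour of a pair of (mixture - tumour) / (liver - tumour) on the linear scale. Correlations across samples had permutation tests with 100000 resamples. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.

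Named genes were chosen by a rule fixed before the data were examined: for livers against tumours, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap; for the mixtures, the 10 largest rises and 5 largest falls called at 5%; for each comparison of liver sets, 5 and 5; for the slopes on the index, 10 and 10 outside the index list; for metastatic biopsies against tumours, 10 and 10; the 2 largest changes of each list; and ESR1, PGR, ERBB2 and MKI67 throughout. Further list members given as examples (C1QA, C1QB and MSR1 in livers against tumours, KRT7, EPCAM, COL1A1, VCAN, CCNB1, MCM2 and NAT1) were chosen after their values were seen. The tests were tried on simulated data with 200 of 22215 probe sets changed. For livers against tumours, 56% of changes of 1 log2 unit and 90% of changes of 2 were recovered, with 4 false calls. For the liver sets the shares were 49% and 91%, with 4 false calls; for mixtures of 5%, 68% and 85% with 12; for pair 0 at 5%, 51% and 77% with 2. For the slopes, 99% and 100% of changes of 1 and 2 log2 units per unit of the index were recovered, with 9 false calls among 22197 probe sets. In the data only 27 of 354 called positive slopes reached 1, so the recovery of smaller slopes is not known. A calibration was also fitted to values simulated from the same form of curve with an SD of 0.1. Inverting the noise-free values returned the percentages with a mean absolute error of 1.76 points. That value holds the error of the fitted curve only, without array noise or misfit of the curve.

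The alternatives tried were quantile normalization, centring each array on its median, scaling arrays to equal total linear signal, leaving out a dim share of 0.25 of the probe sets, eBayes without trend, adding or removing the pair block, other index lists, the mean over all probe sets of a gene, other curves and calibration sets, other folds between endpoints, leaving out single pairs or replicates, and covariates. Array numbers in the deposited sample names, with a gap of more than 10 between neighbours taken as a new run, gave 2 runs for the development livers, 1 for the validation livers, 4 for pair 0, 9 for pairs 1 to 11 and 3 among the 5 metastatic arrays with numbers; no run held arrays of 2 sample sets, and all 10 arrays of a pair lay in 1 run. Each biopsy was 1 array, so the spread between biopsies holds biological and technical variation together. The number of arrays limits the precision.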

Results

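Gene expression was measured on arrays in 203 RNA samples from human liver, breast cancer, mixtures of both, and metastatic breast cancer biopsies. There were 21 livers of the development set, 10 of the validation set, 39 arrays of pair 0, 110 arrays of pairs 1 to 11 and 23 metastatic biopsies. Array medians lay between 8.03 and 8.62 log2 units. Liver and tumour RNA spread their signal differently: the 100 brightest probe sets held 30.4% ± 3.21 of the linear signal in undiluted livers and 17.6% ± 2.11 in undiluted tumours (SD, n = 11 each). Between technical triplicates of pair 0 the median SD of a probe set was 0.309 at 0% and 0.417 at 100% liver, against 0.606 between 11 tumours and 0.601 between 11 livers. The number of arrays limits the precision of every up or down count.

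The first comparison asked which transcripts separate liver from breast cancer, the step from which a liver index is built. Livers were marked by secreted and metabolic hepatocyte genes. AGXT, the peroxisomal enzyme that removes glyoxylate, rose by 11.23 ± 0.83 log2 units (SE), from 5.03 ± 3.04 in tumours to 16.26 ± 0.41 in livers (SD, n = 11 each; adjusted p = 3.93e-11, limma). ALB, serum albumin, rose by 9.76 ± 1.21, from 7.93 ± 4.44 to 17.69 ± 0.40 (adjusted p = 3.34e-07). KRT19, a keratin of glandular epithelium, fell by 9.52 ± 0.33, from 13.37 ± 1.02 in tumours to 3.84 ± 0.58 in livers (adjusted p = 4.35e-16). Of the 22215 probe sets 4841 were higher and 5477 lower in liver; 2568 and 3722 of the changes exceeded 2-fold. Without the dimmest probe sets 4738 were higher and 4066 lower, so the majority of calls turned.

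The other large rises among genes with separate groups were AMBP (11.14 ± 1.00), APOC3 (11.00 ± 1.03), FABP1 (10.68 ± 0.93), PLG (10.49 ± 0.79), SERPINC1 (10.36 ± 0.80), APOA1 (10.23 ± 0.89), KNG1 (10.21 ± 0.81), HPD (10.03 ± 0.67) and RBP4 (9.96 ± 1.08), which encode plasma carriers, coagulation and kinin factors, a fatty acid binding protein and a tyrosine-degrading enzyme. All 18 measured genes of the liver index rose, as did 27 of 27 of the second index, 23 of 23 plasma proteins, 16 of 16 urea cycle and amino acid genes, 13 of 13 bile acid genes and 12 of 12 acute phase genes, with the same counts adjusted over the list alone. CYP2E1 (9.57 ± 0.90) and CYP3A4 (9.23 ± 0.73) led the 16 of 17 xenobiotic genes that rose. BAAT, which conjugates bile acids, rose by 8.18 ± 0.54, SLCO1B1, a hepatocyte uptake transporter, by 6.81 ± 0.45, ITIH4 by 9.44 ± 0.68 and the fibrinogen chain gene FGG by 9.02 ± 0.99. Camera called each of these lists upward (adjusted p from 4.72e-24 to 1.98e-10). The calls of the xenobiotic, urea and bile acid lists held with an estimated correlation (adjusted p = 0.0472, 0.0359 and 0.0359); those of the liver index (adjusted p = 0.109 with an estimated correlation), the plasma proteins (0.109), the acute phase (0.0875) and the second index (0.0514) did not.

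Markers of other liver cells were higher too. All 9 genes of sinusoidal endothelium rose, led by FCN3 (6.22 ± 0.52), a lectin of the complement system, and CRHBP (4.83 ± 0.35), and the list was called (adjusted p = 1.56e-08; adjusted p = 0.0359 with an estimated correlation). Of 8 Kupffer cell and macrophage genes 5 rose, among them the scavenger receptor MARCO (4.31 ± 0.48) and CD5L (4.18 ± 0.31), while C1QA (0.05), C1QB (0.01) and MSR1 (-0.17) were not called (list adjusted p = 0.0124; adjusted p = 0.329 with an estimated correlation). Of 8 cholangiocyte genes 5 fell and 1 rose, 6 and 1 adjusted over the list alone (adjusted p = 0.000299; 0.0216 with an estimated correlation). Its falling members KRT7 (-4.97), KRT19, EPCAM (-5.32) and CLDN4 (-5.44) are also expressed by breast epithelium.

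Tumours were marked by epithelial, stromal, cell cycle and lymphoid genes. Besides KRT19, the largest falls in liver were AGR2 (-7.35 ± 0.74), a secretory pathway protein of luminal cells, CRIP1 (-6.96 ± 0.49), DUSP4 (-6.67 ± 0.58), FXYD3 (-6.57 ± 0.42), KRT15 (-6.41 ± 0.74), TPM2 (-6.35 ± 0.42), COMP (-6.20 ± 0.55), SOX4 (-6.07 ± 0.65) and CLDN4 (-5.44 ± 0.33). A second probe set of FXYD3 (0.27) and of TPM2 (-0.11) was not called. Among 19 stromal genes 17 fell, with COL11A1, a fibrillar collagen, at -5.07 ± 0.60 and FAP, fibroblast activation protein, at -4.65 ± 0.47, whereas FN1, which hepatocytes secrete, rose by 2.04 (list adjusted p = 1.18e-10; adjusted p = 0.126 with an estimated correlation). Proliferation genes fell in 19 of 23 cases, including TOP2A (-4.26 ± 0.62) and CDK1 (-3.40 ± 0.41; list adjusted p = 2.92e-06; adjusted p = 0.261 with an estimated correlation). Of 21 luminal genes 12 fell and 1 rose, 13 and 1 adjusted over the list alone (adjusted p = 0.000709; adjusted p = 0.391 with an estimated correlation). Of 18 lymphocyte genes 11 fell, with the plasma cell genes POU2AF1 (-3.15 ± 0.48) and TNFRSF17 (-3.07 ± 0.56; list adjusted p = 0.0025; adjusted p = 0.45 with an estimated correlation). Of 9 basal genes 6 fell and 1 rose, 8 and 1 adjusted over the list alone, led by GABRP (-4.92 ± 0.77) and CDH3 (-4.46 ± 0.78), while EGFR rose by 3.11 (list adjusted p = 0.0346; adjusted p = 0.391 with an estimated correlation).

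The clinical marker genes separated both tissues less clearly. ESR1, the oestrogen receptor gene, had 11.07 ± 0.54 in livers and 10.91 ± 2.53 in tumours and was not called (0.16 ± 0.70, adjusted p = 0.879), although 2 of its other probe sets were lower in liver (-2.24, adjusted p = 0.0091, and -2.50, adjusted p = 0.00368). PGR, the progesterone receptor gene, fell by 2.97 ± 0.82 (adjusted p = 0.00438) and MKI67 by 0.49 ± 0.19 (adjusted p = 0.0417); of the other MKI67 probe sets 1 fell by 2.86 (adjusted p = 8.54e-06), and those at -0.21 and -0.65 were not called. ERBB2 was not called (-0.77 ± 0.35, adjusted p = 0.0699), but was called lower with quantile normalization (-1.09) or equal total signal (-1.77), and its other probe set fell by 2.27. These 4 genes as a list gave 2 falls, 3 adjusted over the list alone, and no camera call (adjusted p = 0.288). The HER2 amplicon had 1 rise, PGAP3 (1.01 ± 0.18), and 3 falls, among them TCAP (-1.09 ± 0.32, not called after quantile normalization), and was not called (adjusted p = 0.35).

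None of the adipocyte, lung, skin, muscle, brain and blood lists was called by camera. Single genes are to be read against all 11963 genes, of which 3009 were called higher and 2876 lower in liver. Of 12 adipocyte genes 5 rose and 1 fell (adjusted p = 0.081); the largest rises were RBP4 and ADH1B (6.84 ± 0.54), which hepatocytes also express. Lung genes had 1 rise and 2 falls of 7, with LAMP3 at -2.57 ± 0.62 (adjusted p = 0.857), skin 3 rises of 9, with DSG1 at 2.51 ± 0.37 (adjusted p = 0.505), and muscle 1 rise and 3 falls of 11, with TNNT1 at -2.50 ± 0.73 (adjusted p = 0.652). The 8 brain genes had 1 rise and 2 falls, ENO2 at -3.72 ± 0.44, with a median of 0.43, a mean of -0.33 and a camera direction downward (adjusted p = 0.911). HBB, beta globin, rose by 3.54 ± 0.43 and S100A12 by 0.95 ± 0.22 (-0.052 with equal total signal), the only 2 of 8 blood genes called (list adjusted p = 0.593). Of 14 early response genes 6 rose, such as FOSB (2.31 ± 0.77), and 2 fell, such as IER3 (-2.36 ± 0.43; list adjusted p = 0.498). Ribosomal protein genes rose in 9 of 11 cases, but RPL3 (1.22 ± 0.19) turned to -0.19 and RPS6 (0.83 ± 0.19) to -0.60 with quantile normalization, and RPS6 to -0.17 with equal total signal (list adjusted p = 0.0065; adjusted p = 0.391 with an estimated correlation). Equal total signal moved the median of all probe sets from -0.10 to -1.11 and the counts to 1463 higher and 15628 lower, so directions of moderate changes are relative to the authors' scaling.

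**Figure D1:**
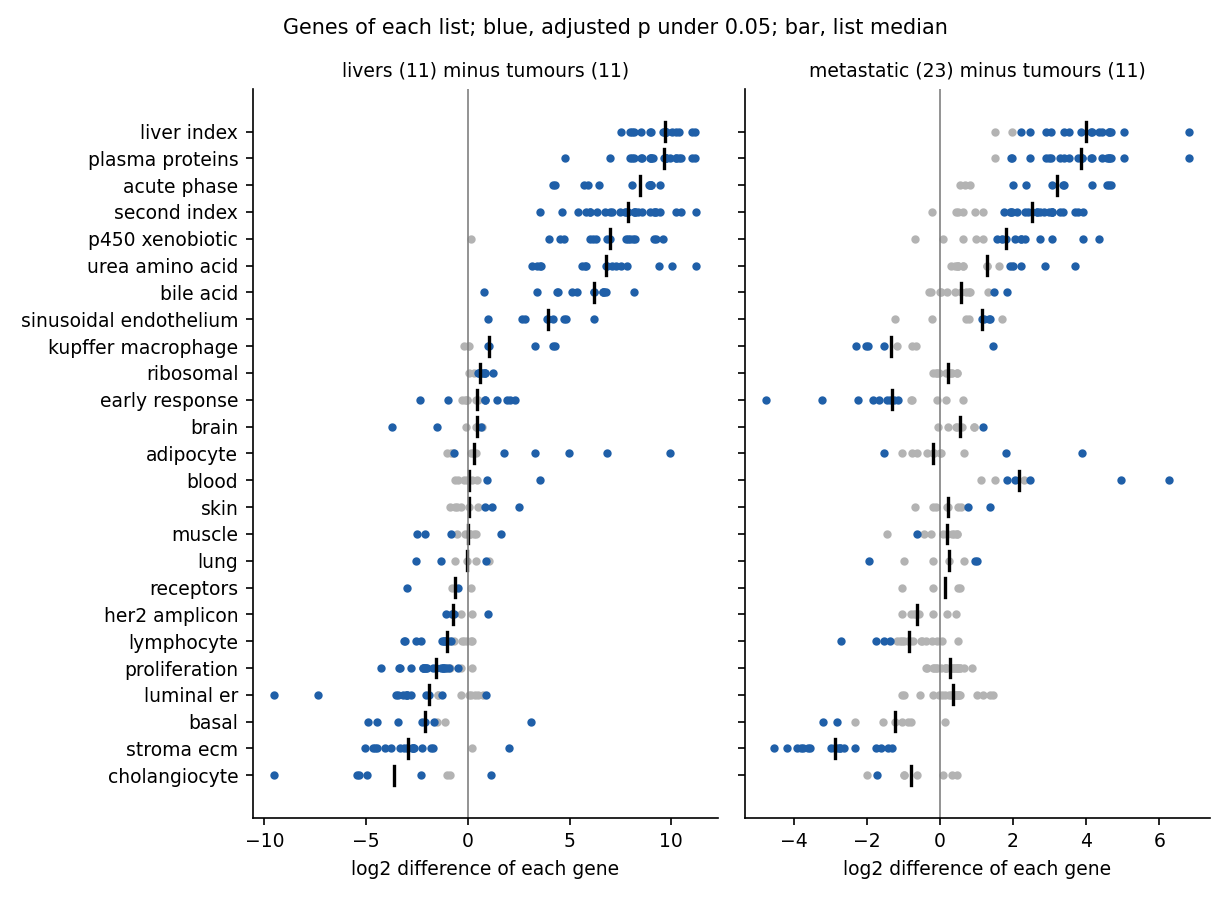
Log2 difference of each gene of the 25 lists, livers minus tumours of pairs 1 to 11 on the left and metastatic biopsies minus those tumours on the right, with 1 point per gene, blue where the adjusted p was under 0.05, and a bar at the list median. The 18 index genes lie far to the right in livers and less far in metastatic biopsies, all 19 stromal genes lie to the left in metastatic biopsies, and ribosomal proteins such as RPL3 and RPS6 lie to the right in livers as deposited but to the left with quantile normalization.

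Whether liver genes found in 1 set of livers hold in another was asked with 2 splits that share no array. The development livers against 6 tumours gave 4649 probe sets up and 4828 down, and the validation livers against 5 other tumours gave 3943 and 4449. Of the 4649 up in the first split 3268 were also up in the second, where independent lists would share 825, and of the 4828 down 3214 were also down, against 967; 11 were called in opposite directions. Across probe sets, which are not independent replicates, log2 changes correlated with r = 0.911. In both splits the 18 index genes rose. With quantile normalization the ribosomal genes named by size turned direction here as well: RPS23 (-0.54) and RPL3 (-0.46) in the development split, and RPS23 (-0.23) and RPL27 (-0.12) in the validation split.

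The liver sets themselves were then set against each other. Between validation and development livers called differences went both ways. SET, a chromatin and phosphatase regulator, was higher by 1.86 ± 0.13 (13.82 ± 0.42, n = 10, against 11.96 ± 0.30, n = 21; adjusted p = 4.63e-12), and ALDOA, the glycolytic aldolase, fell by 3.54 ± 0.36 (6.97 ± 1.59 against 10.51 ± 0.58; adjusted p = 1.91e-08). RAD21L1 (2.46 ± 0.66), TRPC4 (1.91 ± 0.56), RCAN3 (1.78 ± 0.52) and NUP62 (1.66 ± 0.48) were also higher. Even in the validation livers RAD21L1 (4.36 to 6.70), TRPC4 (3.16 to 6.95) and RCAN3 (3.19 to 6.90) lay under the array medians of 8.09 to 8.18. These are changes of dim probe sets, where noise is not excluded. NUP62 lay at 8.00 to 9.70. NKG7 (-2.68 ± 0.67), ERI3 (-2.47 ± 0.36), SLC4A2 (-2.41 ± 0.33) and MRPL4 (-2.39 ± 0.31) were lower. Of 8 Kupffer cell genes 3 fell, among them the complement genes C1QA (-1.16 ± 0.17) and C1QB (-0.96 ± 0.19), and of 9 sinusoidal genes 2 fell, including STAB1 (-1.02 ± 0.15). Hepatocyte genes moved both ways: ARG1, the urea cycle arginase, rose by 0.75 ± 0.17, while AGXT (-0.94 ± 0.16), ITIH4 (-0.76 ± 0.21) and CYP27A1, a bile acid enzyme (-1.03 ± 0.15), fell, and ALB was not called (0.47, adjusted p = 0.149). No list was called; the lowest adjusted p was 0.0841, for sinusoidal endothelium. In all 589 probe sets were higher and 1144 lower in the validation livers, a split that became 788 and 908 with median-centred arrays and 254 and 1310 with equal total signal. With the ACTB difference between 3-prime and 5-prime signal as a covariate 964 probe sets were called, 842 of them among the 1733. The 3-prime signal of ACTB exceeded its 5-prime signal by 2.51 ± 0.29 log2 units in validation and 1.88 ± 0.53 in development livers. For GAPDH this difference was 1.132 ± 0.236 and 1.196 ± 0.247, so it was not higher in validation livers. No array run held livers of both sets, so set and run cannot be told apart.

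Against the development livers, the 11 undiluted livers of the pairs had 1017 probe sets higher and 1166 lower (1360 and 614 with equal total signal). FNDC11 (2.92 ± 0.47), CRCT1 (2.43 ± 0.50), GADD45GIP1 (2.18 ± 0.55), EIF2S3 (2.02 ± 0.38) and RGS11 (2.00 ± 0.39) were higher. AOAH, which inactivates bacterial lipopolysaccharide (-2.73 ± 0.28), RPRD2 (-2.61 ± 0.33), TRO (-2.54 ± 0.49), PTPRS (-2.36 ± 0.38) and BRIX1 (-2.33 ± 0.54) were lower. Of 17 xenobiotic genes 4 fell, 6 adjusted over the list alone, with UGT2B4, a bile acid glucuronidating enzyme, at -0.79 ± 0.16 and the alcohol dehydrogenase ADH1A at -0.69 ± 0.15; the list was called downward (adjusted p = 0.0341; adjusted p = 0.854 with an estimated correlation). CPS1, the entry enzyme of the urea cycle, fell by 0.71 ± 0.20, and ABCB11, the bile salt export pump, rose by 0.94 ± 0.25. The ACTB difference between 3-prime and 5-prime signal was 0.598 in these livers, and with it as a covariate 105 probe sets were called, 92 of them among the 2183. It was 1.88 in the development livers, and the ranges hardly overlapped (up to 1.28 against 1.19 and above). The covariate thus nearly restated the sets, and no array run held livers of both. The drop in calls therefore cannot tell RNA quality from set or run.

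How little liver RNA is detectable in a tumour was asked with the mixtures. At 5% liver RNA the genes with the largest called rises, named here, were hepatocyte genes, and most of them encode plasma proteins. ALB rose from 7.93 ± 4.44 to 15.29 ± 0.34 (SD, n = 11 pairs), by 7.36 ± 1.05 (SE; adjusted p = 0.00062, limma with the pair as a block), in 11 of 11 pairs. APOC3 (6.79 ± 0.84), AMBP (6.24 ± 0.80), RBP4 (5.77 ± 0.87), APOA2 (5.74 ± 0.69), APOA1 (5.68 ± 0.70), AGXT (5.67 ± 0.64), APOH (5.66 ± 0.71), CYP2E1 (5.61 ± 0.72) and PLG (5.51 ± 0.64) followed, each higher in 11 of 11 pairs. In all 359 probe sets were called at 5%, 8 of them lower. Without the pair block limma called 163, all of them higher, and 1869 had an unadjusted p under 0.05 with the block.

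By list, 18 of 18 index genes, 23 of 23 plasma proteins, 26 of 27 second index genes, 16 of 17 xenobiotic genes, 11 of 16 urea cycle genes, 10 of 12 acute phase genes and 7 of 13 bile acid genes rose at 5%; adjusted over the list alone, 27 second index, 15 urea cycle, 12 acute phase and 9 bile acid genes rose. Each list was called, with an adjusted p of 0.0064 with an estimated correlation. Of 9 sinusoidal genes 2 rose, 4 adjusted over the list alone (adjusted p = 3.12e-06; 0.00965 with an estimated correlation), and of 8 Kupffer cell genes 1, 2 adjusted over the list alone (adjusted p = 0.0788). No gene of the 19 stromal, 23 proliferation or 21 luminal genes was called by limma at 5%. The 5 called falls were CHL1 (-1.94 ± 0.46, 9 of 11 pairs), IQCH (-1.33 ± 0.32, 9 of 11), PDX1 (-1.27 ± 0.30, 11 of 11), HSPA1L (-1.03 ± 0.23, 10 of 11) and S1PR1 (-0.43 ± 0.10, 10 of 11); between 3 and 5 of them lost their call when any 1 pair was left out, and all 5 without the block or without the 3 pairs with a shared code described with the index.

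Tumour transcripts declined at higher levels. The counts up and down were 561 and 59 at 10%, 740 and 81 at 15%, 852 and 175 at 20%, 1060 and 376 at 25%, 2141 and 2277 at 50%, 3161 and 4385 at 75%, and 3846 and 4934 at 90%. With equal total signal they were 493 and 161, 657 and 407, 778 and 885, 920 and 2153, and 1414 and 7081 at 10, 15, 20, 25 and 50%. With quantile normalization they were 504 and 156, 673 and 350, 796 and 625, 986 and 1279, and 1789 and 3784, and with median-centred arrays 501 and 139, 668 and 286, 787 and 358, 949 and 984, and 1789 and 3634. Stromal genes were the first tumour list to be called, with 5 of 19 lower at 25%, 9 adjusted over the list alone (adjusted p = 2.03e-05; 0.0185 with an estimated correlation), and 15 lower at 50% (0.0441 with an estimated correlation). At 50% COL11A1 (-0.83), COL1A1 (-0.57) and VCAN (-0.65) were among the falls. Proliferation genes had 7 of 23 lower at 50%, among them TOP2A (-0.69), CCNB1 (-0.54) and MCM2 (-0.54; list adjusted p = 0.0018; adjusted p = 0.103 with an estimated correlation). Luminal genes had 5 of 21 lower at 50% without a list call (adjusted p = 0.0966) and 10 at 75% (adjusted p = 0.0104; adjusted p = 0.127 with an estimated correlation).

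Of the receptor genes only ERBB2 and PGR were called, at the highest levels and with the pair block. ESR1 was not called at any level, from -0.05 ± 0.06 at 5% to 0.45 ± 0.38 at 90% (adjusted p = 0.37), while its SD between pairs went from 2.53 at 0% to 1.94 at 50% and 1.15 at 90%. ERBB2 fell by 0.49 ± 0.13 at 75% (adjusted p = 0.0119) and by 0.56 ± 0.13 at 90% (adjusted p = 0.00353), and PGR fell by 2.30 ± 0.54 at 90% (adjusted p = 0.00344); without the block none of these 3 calls remained. MKI67 was -0.44 ± 0.20 at 90% (adjusted p = 0.0925), and with equal total signal it was called from 50% on, at -0.43. ALB differed from the undiluted tumours by 7.53 at 10%, 8.24 at 50% and 8.94 at 90%.

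**Figure D2:**
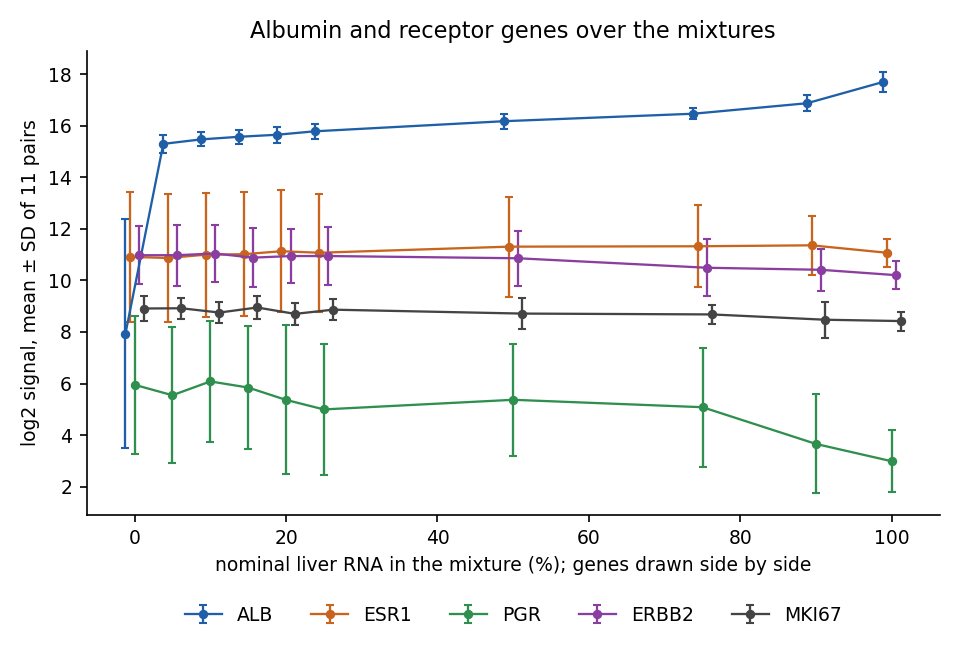
Mean log2 signal and SD over the 11 pairs of ALB, ESR1, PGR, ERBB2 and MKI67 against the nominal percentage of liver RNA. ALB rises by 7.36 log2 units between 0 and 5%, and ESR1 keeps its mean while its SD falls from 2.53 to 1.15 at 90%.

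In pair 0, with 3 technical replicates per level, ALB rose from 8.10 ± 0.45 to 15.02 ± 0.08 at 5% (SD, n = 3; by 6.92 ± 0.18, limma), and 269 probe sets rose and 1 fell. All 18 index genes and 23 plasma protein genes rose again, lists that share most of their genes. ESR1 (-0.22), PGR (-0.61), ERBB2 (0.17) and MKI67 (-0.02) were not called. The counts grew to 1177 and 242 at 50% and 3462 and 3767 at 100%. The arrays of 5 to 20% lay in other runs than those of 0%, so smaller changes at those levels can hold a run effect, while the 25% arrays shared the runs of 0%. The replicates show technical spread only.

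The calibration curve was asked to turn the mean level of the index genes into a percentage. In pair 0 the index was 6.66 ± 0.08 at 0%, 11.82 ± 0.04 at 5%, 12.68 ± 0.04 at 10%, 13.95 ± 0.02 at 25%, 14.89 ± 0.07 at 50%, 15.57 ± 0.19 at 75% and 16.73 ± 0.15 at 100% (SD, n = 3 technical replicates). The curve passed through 6.67 at 0%, 15.04 at 50% and 16.22 at 100%, where the arrays lay 0.51 above it. Its residual SD was 0.207, against 0.101 between technical replicates; it was 0.0453 with quantile normalization and 0.0721 with 20 genes taken from the development split.

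**Figure D3:**
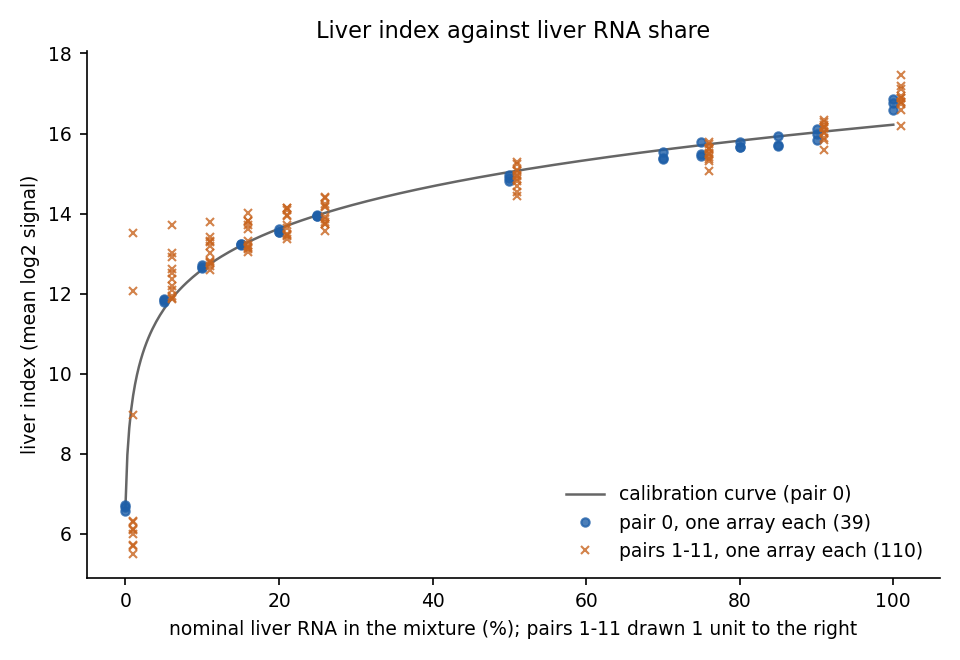
Liver index (mean log2 signal of 18 hepatocyte genes) against the nominal percentage of liver RNA, with the 39 arrays of pair 0 as points, the 110 arrays of pairs 1 to 11 as crosses drawn 1 unit to the right, and the calibration curve fitted to pair 0. The index of pair 0 climbs from 6.66 to 11.82 between 0 and 5% and reaches 16.73 at 100%.

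The error of that curve was measured in the 11 other pairs. Over 110 arrays the estimate missed the nominal percentage by 4.71 points on average (SD over pairs 2.42, range 1.80 to 9.16), with a median of 3.31, and 98 arrays lay within 10 points. Over the mixed levels alone it was 5.57 points. At 5% the estimate was 9.82 ± 4.58 (SD, n = 11), 4.82 points too high and too high in 11 of 11 pairs (exact sign-flip test, adjusted p = 0.00977). At 10% it was 4.12 points too high, in 10 of 11 pairs (adjusted p = 0.00977, exact), a call lost with quantile normalization, with a linear curve and with a calibration on the other pairs. At 75% the error was -8.23 points, with 9 of 11 pairs too low (adjusted p = 0.0228, exact); it was no longer called with quantile normalization (-2.05), straight lines between levels (-2.06), genes from the development split (-3.65), a linear curve (-5.90) or without technical replicate 1 of pair 0 (-6.00). Errors at 0% (2.37), 15% (3.27), 20% (2.31), 25% (1.09), 50% (-3.62), 90% (1.197) and 100% (-0.175) were not called (adjusted p from 0.122 to 1). Estimates were held between 0 and 100, so at 0% only 3 and at 100% only 1 of 11 pairs had any error. In this setting the test could therefore call neither of these levels. Other settings called the error at 50% (-10.01 with a calibration on the other pairs, adjusted p = 0.0146, exact), at 100% (-5.71 with quantile normalization, adjusted p = 0.0293, exact) and at 0% (1.97 with genes from the development split, adjusted p = 0.0358, exact). With a calibration on the other pairs the error at 75% was -15.5 points, too low in 11 of 11 pairs.

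**Figure D4:**
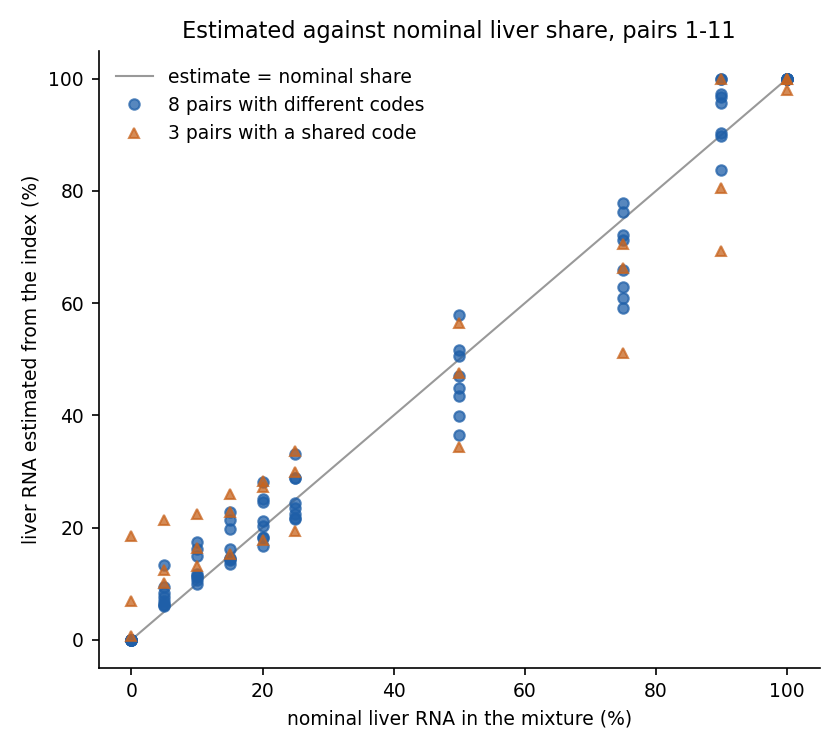
Estimated against nominal percentage of liver RNA for the 110 arrays of pairs 1 to 11, with circles for the 8 pairs whose titles carry different codes, triangles for the 3 pairs with a shared code, and the line of equality. The triangles lie above 0 in undiluted tumours, up to 18.5%, where all circles lie at 0.

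The index rose from 0% to 5% by 4.99 ± 2.43 (SD, n = 11 pairs), in 11 of 11 pairs (exact sign-flip test, p = 0.000977, the smallest it can give). The titles give each liver and each tumour of a pair a code, and in 3 of the 11 pairs both carry the same code; what the codes stand for is not stated. In those 3 pairs the rise was 1.57 (0.22 to 3.96), against 6.27 ± 0.57 (5.59 to 7.30) in the other 8. Their undiluted tumours had an index of 11.51 (8.96 to 13.51), against 5.97 ± 0.30 (5.50 to 6.33) in the others (exact permutation test, 3 against 8, p = 0.00606, the smallest it can give), and the second index gave 9.29 against 6.17 with the same p. These 3 pairs have odd numbers, and ALB rose by 7.91 ± 1.02 in the development split, which holds the tumours of odd pairs, and by 12.71 ± 0.40 in the validation split. Without these pairs the mean absolute error of the estimate was 3.52 points.

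A measure of liver share that uses no index set each mixture between its own endpoints. Over the 1850 to 2678 probe sets at least 8-fold apart, the effective liver fraction was 4.70% ± 1.66 at 5%, 6.75% ± 1.34 at 10%, 13.9% ± 2.89 at 25%, 28.99% ± 4.97 at 50%, 49.1% ± 5.75 at 75% and 69.3% ± 4.62 at 90% (SD, n = 11 pairs). At 50% it lay below nominal in 11 of 11 pairs (exact sign-flip test, p = 0.000977, the smallest it can give). Liver-high genes alone gave 23.9% and tumour-high genes alone 39.02% at 50%. With equal total signal the fraction at 50% was 44.9% ± 4.95, below nominal in 9 of 11 pairs (exact sign-flip test, p = 0.0107), 39.6% for liver-high genes alone (11 of 11 pairs below, p = 0.000977, exact) and 46.7% for tumour-high genes alone (8 of 11 below, p = 0.0645, exact). At low levels the direction turned with the probe sets and with the scaling. As deposited, tumour-high genes alone gave 11.5% at 5%, above nominal in 11 of 11 pairs, and liver-high genes alone 3.21%. The same endpoint arrays chose these probe sets and set the scale. Noise in them can therefore raise tumour-high and lower liver-high fractions at low levels, and how much of the turn this makes was not tested. At 5% the fraction was 10.2% with equal total signal and 7.36% with quantile normalization, and at 10% it was 13.9% with equal total signal, above nominal in 11 of 11 pairs each.

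Metastatic biopsies were the samples in which liver content was unknown. Their index was 11.25 ± 2.16 (SD, n = 23; 6.20 to 15.68), between the undiluted tumours (7.48 ± 2.80; median 6.13) and the livers, which had 17.003 ± 0.33 in the development set, 17.12 ± 0.40 in the validation set and 16.87 ± 0.33 in the pairs. The estimated liver content had a median of 4.38% with quartiles of 1.25 and 11.1% and a range of 0 to 73.7%. With other settings the median ran from 2.90% (quantile normalization) to 5.98% (genes from the development split). In the main setting 6 biopsies lay under 1%, 6 above 10% and 1 above 50%. The count under 1% was 3 with the second list, 3 with genes from the development split and 1 with straight lines between levels. No mixture lay between 0 and 5%, so estimates in that range rest on the form of the curve. The background measured the same way in the 11 undiluted tumours reached 18.5%, and 3 metastatic biopsies exceeded it, or 1 with quantile normalization or equal total signal. Without the 3 tumours of shared-code pairs the background was 0% and 22 exceeded it. That 0% is the lower limit of the estimate: the index of the other 8 tumours (5.50 to 6.33) lay under the 6.67 of the curve at 0%. With genes from the development split this background was 1.08% and 20 exceeded it. At a nominal 5% the mixtures were estimated 4.82 points too high, and 3.02 points without the pairs with a shared code, whose undiluted tumours already held liver transcripts.

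**Figure D5:**
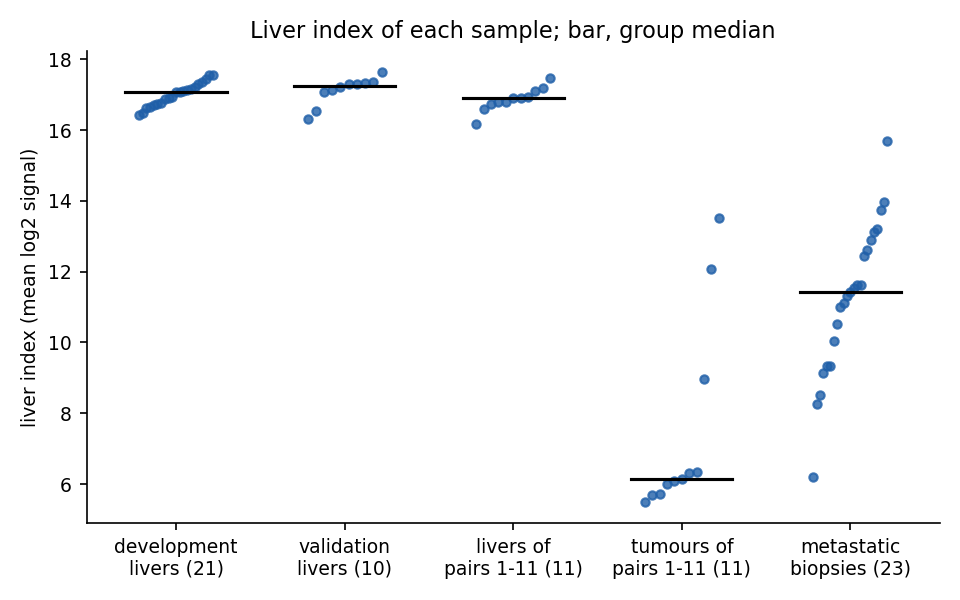
Liver index of each sample (mean log2 signal of 18 hepatocyte genes) in undiluted tumours, metastatic biopsies and the 3 sets of livers, with a bar at the group median. Metastatic biopsies spread from 6.20 to 15.68, and livers lie between 16.18 and 17.63.

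The second index, of 27 other hepatocyte genes, followed the first across the 23 biopsies with Pearson's r = 0.979 and Spearman's rho = 0.986 (permutation p = 1e-05 each, the smallest they can give), and with r = 0.987 without the 2 samples farthest from the median index. Within the 2 series of sample titles r was 0.986 (n = 14) and 0.974 (n = 9, permutation p = 2e-05). The slope was 0.74.

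Which other genes moved with the index across the metastatic biopsies was asked next. Per unit of the index, RBP4, the retinol carrier, rose by 1.35 ± 0.13 log2 units (SE, n = 23), AGXT by 1.34 ± 0.09, PLG by 1.25 ± 0.13, ITIH4 by 1.22 ± 0.14, FABP1 by 1.21 ± 0.07, ORM1 by 1.18 ± 0.09, SLC2A2, the hepatocyte glucose transporter, by 1.14 ± 0.11, TF by 1.08 ± 0.07, C1S by 1.03 ± 0.08 and C8G by 1.01 ± 0.12. Genes of the lists for other liver cells moved along: CD14 (0.64 ± 0.12) and CD163 (0.42 ± 0.10) of the Kupffer cell list and FCN3 (0.77 ± 0.10) and LYVE1 (0.42 ± 0.11) of sinusoidal endothelium. Macrophages and vessels of a tumour can express such genes too, so the cells they came from are not known. In all 354 probe sets had a called positive and 13 a called negative slope. Of 235 genes with a positive slope 223 (94.9%) were also higher in liver than in tumour, against 25.0% of all 11945 genes, and 3 were lower.

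By list, 25 of 27 second index genes, 8 of 8 plasma proteins outside the index, 9 of 9 acute phase, 14 of 16 xenobiotic, 7 of 14 urea cycle and 7 of 13 bile acid genes had positive slopes; adjusted over the list alone these were 27, 8, 9, 15, 11 and 9. Kupffer cell genes had 4 of 8 and sinusoidal genes 5 of 9, all 8 and all 9 adjusted over the list alone. These 8 lists were called also with an estimated correlation (adjusted p from 6.71e-11 to 0.0155). Of 12 adipocyte genes 2 rose, RBP4 and ADH1B (0.77), both hepatocyte genes (adjusted p = 0.00272; 0.0228 with an estimated correlation). EGFR (0.57 ± 0.12, adjusted p = 0.00933), also higher in liver than in tumour, was the only basal gene called (list adjusted p = 0.0236; adjusted p = 0.426 with an estimated correlation). The 8 blood genes had no call (limma) and a list adjusted p of 0.0262 (adjusted p = 0.5684 with an estimated correlation). The luminal list was called downward (adjusted p = 3.42e-06; adjusted p = 0.276 with an estimated correlation) with none of 21 genes called, ESR1 at -0.30 ± 0.17 (adjusted p = 0.594) and NAT1 at -0.47. The 7 genes with a called negative slope were NIP7 (-0.43), CHRNB1 (-0.31), ZNF107 (-0.31), NIPA2 (-0.30), PPP1CB (-0.25), ARPC3 (-0.18) and TSNAX (-0.18), and none of them was called within either title series, where 134 and 186 probe sets had a positive slope and 2 and 4 a negative one.

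Set against the undiluted tumours, the metastatic biopsies held more transcripts of plasma protein and red cell genes and fewer of stromal genes. Of the plasma protein, blood and stromal lists only the stromal one was called also with an estimated correlation. ALB was higher by 6.80 ± 1.06 (SE; 14.73 ± 2.25, n = 23, against 7.93 ± 4.44, n = 11; adjusted p = 3.55e-05, limma). HBB, beta globin, was higher by 6.25 ± 0.62 (adjusted p = 8.88e-09), with ALAS2, the erythroid haem synthesis enzyme (4.96 ± 0.92), and HBD (4.91 ± 0.79). POSTN, the matrix protein periostin, fell by 4.20 ± 0.37 (adjusted p = 1.37e-09), and LUM, lumican, by 4.53 ± 0.54. In all 1749 probe sets were higher and 1425 lower. Because the biopsies and the pairs are different sample sets, set and biopsy type cannot be told apart, and RNA quality differed with them: the ACTB difference between 3-prime and 5-prime signal was 1.28 in the 8 metastatic samples matched to it and 0.178 in undiluted tumours.

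The other named rises were APOC3 (5.03 ± 1.06), FGG (4.69 ± 0.97), FGB (4.63), AMBP (4.62), HP (4.58) and APOH (4.43). The other named falls were CCN2 (-4.90 ± 0.55), GAS1 (-4.81 ± 0.70), the immediate early gene FOS (-4.75 ± 0.78), INHBA (-4.62 ± 0.53), the immunoglobulin genes IGKC (-4.27 ± 0.73) and IGLC1 (-4.04 ± 0.71), COL6A2 (-4.08 ± 0.72) and RGS1 (-4.02 ± 0.61). All 19 stromal genes fell (adjusted p = 1.33e-37; 0.00174 with an estimated correlation). Of 14 early response genes 9 fell, 10 adjusted over the list alone, with FOSB at -3.22 ± 0.60 and DUSP1 at -2.23 (adjusted p = 5.14e-08; adjusted p = 0.0514 with an estimated correlation). Of 8 blood genes 5 rose, 7 adjusted over the list alone (adjusted p = 2.09e-06; adjusted p = 0.211 with an estimated correlation). Hepatocyte lists rose in part: 16 of 18 index, 22 of 23 plasma protein, 21 of 27 second index, 11 of 17 xenobiotic, 9 of 12 acute phase, 5 of 16 urea cycle and 2 of 13 bile acid genes, or 18, 23, 23, 12, 10, 7 and 3 adjusted over the list alone (adjusted p between 0.211 and 0.601 with an estimated correlation).

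Immune and basal markers were lower in part. Of 8 Kupffer cell genes 4 fell, among them C1QB (-2.30 ± 0.36) and MSR1 (-2.03 ± 0.50), and 1 rose, CD5L (1.44; list adjusted p = 0.000349; adjusted p = 0.224 with an estimated correlation). Of 18 lymphocyte genes 4 fell, led by TNFRSF17 (-2.70 ± 0.45) and CD3G (-1.74; adjusted p = 4.96e-05; adjusted p = 0.291 with an estimated correlation). Of 9 basal genes 2 fell, 5 adjusted over the list alone, including KRT14 (-3.21 ± 0.86; adjusted p = 0.000614; adjusted p = 0.224 with an estimated correlation). Sinusoidal genes rose in 4 of 9 cases, such as CLEC4M (1.36; adjusted p = 0.0148; adjusted p = 0.387 with an estimated correlation). No proliferation, luminal, HER2 amplicon or ribosomal gene was called by limma, and ESR1 (0.48, adjusted p = 0.709), PGR (-1.03, 0.383), ERBB2 (-0.18, 0.836) and MKI67 (0.56, 0.0875) stood near the tumours. Of 12 adipocyte genes 2 rose and 1 fell (median -0.18, mean 0.14, camera downward), of 7 lung genes 2 rose and 1 fell (median 0.24, mean -0.04, camera upward), and of 11 muscle genes 1 fell (median 0.20, mean -0.06, camera downward); none of the 3 lists was called. With the index as a covariate 211 probe sets were called higher and 560 lower, 693 of them among the 3174 called without it; AGXT went from 3.70 ± 1.04 to -0.83. With equal total signal the counts were 766 and 2392, and with the second title series alone 977 and 1211.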

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

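The tests of carry-over unrelated to the code and of array runs, the comparisons with equal total signal, those without the shared-code pairs, the ACTB covariate, the ACTB correlation over called probe sets only, and the reading of messenger RNA content from liver-high probe sets were chosen only after the results were seen.

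In the validation livers the log2 signal of NKG7, a gene of cytotoxic lymphocytes, was 8.10 in 1 sample, with the next at 5.08 and the lowest at 2.48. The gap was 0.538 of the range, above Dixon's critical value for 10 samples. Of 22 measures tested this way it was the only 1 above that value, and chance picks about 1 in 20 groups.

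The index change from 0% to 5% liver differed between pairs whose titles give liver and tumour the same code and the other pairs by -4.69 (exact permutation test, 3 against 8 pairs, p = 0.00606, the smallest it can give). With 20 genes taken from the development split it was -0.24 (exact p = 0.339), but the tumours of that split include these 3, so genes raised in them were selected against. The undiluted tumours of these 3 pairs already held hepatocyte transcripts, with an estimated liver content of 8.70% (0.663 to 18.5), against 0 in the other 8.

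For that pattern the values argue against expression by the tumour cells in 1 tumour, that with the highest index. There Kupffer and sinusoidal genes stood at 13.7% of their liver level and index genes at 9.20%, a ratio of 1.49. Hepatocyte genes expressed by tumour cells would leave the genes of other liver cells near 0. Of those genes 7 of 11 lay above the other tumours, against 18 of 18 index genes. In the tumours of pairs 7 and 5 the ratios were 1.03 (6 of 9 genes above) and 2.42 (3 of 8). Macrophages and vessels of a tumour can express such genes too, so expression by the tumour cells is not excluded. For carry-over of liver RNA unrelated to the code, the exact permutation p of 0.00606 restates the difference that defined the pattern and excludes nothing. Liver tissue in the tumour samples would give every hepatocyte list a like share; 1 of 3 tumours had a list outside 0.5 to 2 times the index share, and it was the tumour with the lowest share, where the index genes stood at 0.60% and the urea cycle genes at -0.0132%. Liver tissue in the sample therefore stays a candidate explanation, and with no statement of what the codes mean, liver taken along with the tumour and carry-over of liver RNA cannot be told apart.

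The liver-tumour difference itself differed between the development and the validation split in 123 probe sets (70 larger and 53 smaller in the validation split), and in 214 (86 and 128) without the shared-code pairs. The 3-prime minus 5-prime signal of the ACTB control probe sets, which no comparison used as an outcome, was 2.51 ± 0.29 in validation livers (SD, n = 10), above the 0.178 of undiluted tumours; for GAPDH it was 1.13 and 0.139.

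The difference between the liver sets may be technical. With RNA degradation as the cause, the ACTB difference as a covariate should remove the calls: 842 of the 1733 called probe sets (48.6%) were also called with it, among 964 in all. The SD of the set difference over the called probe sets went from 0.753 to 0.719, which argues against the ACTB trend as the whole cause. The GAPDH control did not share the ACTB shift. Its 3-prime minus 5-prime signal was 1.132 ± 0.236 in validation and 1.196 ± 0.247 in development livers (SD). By this control the RNA of the validation livers was not more degraded, but it is a single transcript. Across all probe sets the slope on the ACTB difference within development livers correlated with the set difference by r = 0.0156, under the bound of 0.1 set against degradation, but that bound was wrong for the pattern, since probe sets that were not called dilute it: over those called r was 0.284. A part of degradation therefore stays open, and as 0 array runs hold livers of both sets, that part, array run and a biological difference between the sets cannot be told apart.

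Another pattern was that mixtures held less liver signal than their nominal share, 28.99% at 50%. At 5% the direction turned with equal total signal (10.2%), with quantile normalization (7.36%) and, as deposited, in tumour-high probe sets alone (11.5%). The turn in tumour-high probe sets can hold noise of the endpoint arrays that chose them, which was not tested. Less messenger RNA in liver than in tumour RNA, a property of the tissues, needs a ratio alike at every level. Over liver-high and tumour-high probe sets together such a ratio was not found. With equal total signal the ratio went from 1.02 at 25% to 0.546 at 90%, 1.86 times apart and over the bound of 1.5. The levels and the bound were fixed before that test was run, but equal total signal was taken up only after the results were seen. Most of the probe sets in that ratio were tumour-high (1612 to 3272 per pair, against 141 to 692 liver-high). Noise in the endpoint arrays can raise their fractions at low levels. A ratio that falls with the level therefore cannot decide against messenger RNA content. Liver-high probe sets alone met the prediction at the same levels (0.748 to 0.5677, within the bound and under 1). The 5% level, outside those fixed, gave 1.23 with an SD of 0.518 between pairs. Messenger RNA content thus stays open. Array scaling by the authors may account for most of the gap, since equal total signal gave 44.9% ± 4.95 (exact sign-flip p = 0.0107, n = 11); that value lies under the bound of 45% set against scaling as the cause, but by less than its spread, so the part of scaling stays open. Saturation also stays open: the brightest of 4 equal groups of liver-high probe sets gave a lower fraction than the dimmest, by -5.27 points (21.02 against 26.29; exact sign-flip p = 0.0303), and by -13.5 points with equal total signal, but the SD of the first difference between pairs was 6.73.

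Other splits of the samples into groups of the same sizes were drawn, 100 per comparison including the real one; in the mixtures each split exchanged the arrays within pairs and so parted all 11 pairs, and for the slopes the index was shuffled. In each of the following the real split alone (1 of 100) gave as many called probe sets, which makes chance an unlikely source of those counts. Where livers were set against tumours a difference was known beforehand, so the result there adds little. The real and highest other counts were 10318 and 1 for livers against tumours, 9477 and 2342 in the development split, 8392 and 1114 in the validation split, 1733 and 1 between the liver biopsy sets, and 2183 and 1 for pair livers. For the mixtures they were 359 and 0 at 5%, 620 and 1 at 10%, 821 and 1 at 15%, 1027 and 0 at 20%, 1436 and 0 at 25%, 4418 and 1186 at 50%, 7546 and 3623 at 75%, and 8780 and 4412 at 90%. They were 367 and 0 for the slopes and 3174 and 2 for metastatic biopsies against tumours. For pair 0 at 5% the counts were 270 and 5, and its 10 splits were too few for a share under 0.05.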

How the results depend on the processing

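Equal total signal, the ACTB covariate, leaving out the shared-code pairs and single title series were chosen only after the data were seen; the other alternatives were set before the data were examined. Of 194 alternatives to the main results 166 were counted as kept, 16 as weaker, 10 as stronger and 2 as moved. Kept meant the same side of the threshold or, for counts, a total within 1.5 times whatever the balance of up and down. For the calibration, the prediction error and the metastatic median it meant a move under the SD of technical replicates, of pairs and of biopsies. The SD of biopsies was 15.6 points around a median of 4.38%, so that rule could hardly fail. Of 3391 alternatives for named genes and levels 3087 stayed, 249 were weaker, 39 stronger and 16 reversed. The total count of all 16 comparisons stayed within 1.5 times with eBayes without trend, with median-centred arrays and without dim probe sets. Among totals that stayed, the majority of calls turned without dim probe sets for livers against tumours (4738 up, 4066 down) and both splits (4642 and 3445; 3970 and 3289), with median-centred arrays at 25% (949 and 984) and for metastatic biopsies (1579 and 1618), with equal total signal for pair livers (1360 and 614) and metastatic biopsies (766 and 2392), without the shared-code pairs in the development split (3945 and 3684) and at 50% (1713 and 1434), and in title series 2 for metastatic biopsies (977 and 1211). The second deposited table was not run as an alternative because its values were equal.

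Equal total signal gave 17091 called probe sets for livers against tumours, 16695 in the development and 17165 in the validation split, and shifted the median log2 change to -1.11, -1.15 and -1.37. In the mixtures it gave 1663 at 20%, 3073 at 25%, 8495 at 50%, 12176 at 75% and 14071 at 90%. Livers held more total signal (4.42324e+07 against 2.20249e+07), so this scaling lowers every liver value by construction. Quantile normalization gave 2265 at 25%, and the cause was not tested.

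Without the pair block the mixtures gave 163 at 5%, 274 at 10%, 384 at 15%, 501 at 20%, 609 at 25%, 1545 at 50% and 4744 at 75%, since the spread between pairs then entered the error. A block on pair or replicate number changed no other main call. With the ACTB covariate 964 probe sets were called between the biopsy sets (842 shared with the main calls) and 105 for pair livers (92 shared), and without the shared-code pairs 1318 for pair livers. The slopes gave 136 within title series 1 and 190 within series 2, with fewer samples. With the index as a covariate 771 were called in metastatic biopsies (693 shared). The residual SD of the calibration was 0.0721 with derived genes and 0.0453 with quantile normalization; the cause was not tested. Metastatic biopsies above the undiluted tumours numbered 1 with quantile normalization, 1 with equal total signal and 22 without the shared-code pairs, which set the background. The effective fraction at 50% was 46.7 with equal total signal and tumour-high probe sets only, no longer called, and 39.6 with liver-high probe sets only, still called; the cause was not tested.

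Directions reversed in livers against tumours with quantile normalization for RPL3 (-0.19) and RPS6 (-0.60) over the pairs, RPS23 (-0.54) and RPL3 (-0.46) in the development split, and RPS23 (-0.23) and RPL27 (-0.12) in the validation split. With equal total signal they reversed for S100A12 (-0.052) and RPS6 (-0.17) over the pairs, and RPS23 (-0.021) and RPL3 (-0.038) in the development split. With the index as a covariate they reversed in metastatic biopsies for KNG1 (-0.027), AGXT (-0.83), MAT1A (-0.10), SLCO1B1 (-0.47), RBP4 (-0.76) and ADH1B (-0.86), whose rise the covariate takes up.

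Leaving out 1 pair at a time gave 303 to 368 called probe sets at 5% and 512 to 638 at 10%. Leaving out 1 technical replicate of pair 0 gave 215 to 308 at 5%, a mean absolute prediction error of 4.68 to 4.81 points, and a metastatic median of 4.33 to 4.45%. Arrays give no counts; signal near background limits the low end, where 0.0381% of values lay below 0.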

Other observations

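The values with equal total signal were chosen only after the results were seen. At the highest mixed levels the tumour lists had unequal numbers of called genes, a difference between lists that was not tested. At 75% liver 17 of 19 stromal genes were lower than in undiluted tumours (adjusted p = 0.0486 with an estimated correlation), against 13 of 23 proliferation genes (0.279) and 10 of 21 luminal genes (0.127). At 90% the falls numbered 17, 18 and 12. COL1A1, the main collagen chain of tumour stroma, fell by 1.11 at 75% and by 1.87 at 90%, VCAN, a matrix proteoglycan, by 1.25 and 1.98, and the cyclin gene CCNB1 by 0.83 and 1.37 (n = 11 pairs); these were chosen after their values were seen.

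Markers of liver cells other than hepatocytes were called in part in the mixtures. Over all 11963 genes 1387 were called higher at 50% liver, and 182 in pair 0 at 5%. At 50% liver 3 of 8 Kupffer cell genes were higher (adjusted p = 0.00923; adjusted p = 0.282 with an estimated correlation). In pair 0 at 5% liver 3 of 9 sinusoidal genes rose (adjusted p = 3.56e-10; 7.32e-05 with an estimated correlation) and none of the 8 Kupffer cell genes was called by limma, among 844 probe sets with an unadjusted p under 0.05.

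Across the metastatic biopsies the second index rose by 0.74 per unit of the first, by 0.77 in title series 1 and by 0.72 in series 2. The median estimated liver content was 4.72% in title series 1 and 1.58% in series 2. It was 2.90% with quantile normalization, 3.20% with equal total signal, 5.28% with the second list and 5.98% with genes derived from the development split.

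The mean absolute error of the estimate over the 110 arrays ranged from 3.59 points with the second list to 5.63 with a calibration on the other pairs. Of these arrays 8 were held at 0 and 13 at 100. In the undiluted livers of the 3 shared-code pairs the index was 16.58, against 16.99 in the other 8 (exact permutation p = 0.0788).

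The ACTB difference between 3-prime and 5-prime signal was 1.28 in the 8 metastatic samples matched to the control probe sets. In pair 0 it was 0.355 at 0% and 1.07 at 100% liver (n = 3 technical replicates), and in the pairs it was 0.178 at 0%, 0.238 at 50% and 0.598 at 100% (n = 11), so undiluted livers stood higher than their mixtures with tumour.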
